A study of Mus musculus with 12 samples.

How the data were processed

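Transcript levels were measured by bulk RNA sequencing in mouse embryonic stem cells of 4 genotypes with 3 libraries each, 12 libraries in all. The cells were of the IB10 line, derived from 129/Ola mice, and were grown on gelatin with conditioned medium, serum and leukaemia inhibitory factor, without treatment, per the labels. The genotypes were wild type, a knockout of DHX36, a knockout of FANCJ, whose mouse gene carries the symbol Brip1, and the double knockout. Per the labels' protocols, total RNA from cells lysed in TRIzol was made into libraries by a protocol like CEL-Seq2, a method that tags the 3′ ends of polyadenylated transcripts with sample barcodes before samples are pooled.

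The deposited values were whole-number counts per gene and library, not normalised by the authors. The submitters' processing notes name the aligner BWA and the builds GRCm38 and hg38, without versions or roles; every gene tested carried a mouse identifier. Whether a count was a read or a molecule collapsed by its identifier was not given in the sources used here, nor was the handling of strand or of reads with several alignments. The table held 32285 genes and 92 spike-in transcripts. Of the gene identifiers, 32235 matched the GENCODE M21 annotation of GRCm38, from which coordinates were taken. Spike-ins took 4 to 30 counts per library, at most 0.000276% of the total, and were left out of totals and tests.

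Total counts were 4553046, 5792862 and 4284785 in the wild-type libraries, 8736633, 6223087 and 10919405 in the DHX36 knockout, 7900066, 7718734 and 4936662 in the FANCJ knockout and 14721931, 12434083 and 10915924 in the double knockout. Every double knockout library was deeper than every wild-type library, so low genes were measured with less counting error there. To see what depth could change, every library was thinned at random to the total of the shallowest, an alternative chosen after the data were examined. CPM, counts scaled to a common library total, were computed from the deposited counts with the normalised totals. Nothing in the labels says that the libraries of a genotype came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. Nor do they say whether a knockout was 1 clone or several.

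Genes were tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood F test on the counts with normalisation by trimmed means and the default expression filter by genotype, which left 12765 genes. All 12 libraries entered 1 model with genotype as its only term, so that the 4 genotypes shared 1 estimate of the spread. Comparisons were each knockout genotype against wild type, the double knockout against either single knockout, and the interaction, that is, the effect of FANCJ loss without DHX36 minus that with DHX36. Adjusted p-values follow Benjamini and Hochberg over the genes tested, with a threshold of 0.05, and all tests were two-sided. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic.

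Gene groups were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, against all other tested genes, with a preset correlation between genes of 0.01 and adjustment over 26 lists. An estimated correlation was the alternative. The lists held G-quadruplex helicases other than the targeted pair, R-loop factors, Fanconi and homologous recombination genes, p53 targets, S-phase genes, G2 and mitosis genes, naive pluripotency genes, formative and primed pluripotency genes, 2-cell-like genes, markers of neuroectoderm, mesendoderm, primitive endoderm, trophoblast and fibroblasts, interferon-stimulated genes, ATF4 targets, endoplasmic reticulum chaperones, cholesterol genes, glycolysis and hypoxia genes, imprinted genes, germline genes, immediate early genes, Wnt targets, ribosomal proteins, histones and mitochondrial mRNAs. Numbers of changed members are given over all genes tested and adjusted over the list alone. Lists of actin and SRF target genes, simple epithelial keratin and junction genes, fatty acid oxidation genes and nuclear RNAs were added after the data were examined and adjusted over those 4.

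G-quadruplex motifs, 4 runs of at least 3 G separated by loops of 1 to 7 bases, were searched on the sense strand of annotated 5′ and 3′ untranslated regions (UTRs), and the genes with a motif were compared by camera with the other genes searched, with adjustment over the pair of sets. Alternatives were loops of up to 12 bases, a lowess correction of fold changes for UTR GC content with a span of 0.3, and, chosen after the data were examined, the same correction for UTR length. Motifs around transcription start sites were not analysed here.

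Genes were named by a rule. For each comparison with wild type it took the targeted genes, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 20 CPM and no overlap between the libraries of both groups, and up to 4 changed members of each list, by size. For the other comparisons it took 5 rises and 5 falls, without the rule on overlap for the interaction. Among the largest rises and falls, predicted genes and pseudogenes were counted but not named, whereas members of the lists were named whatever their symbol. A few other genes that the rule took are not reported here. List members whose call was lost under some alternative are mostly covered by their list's counts. Groups, comparisons, tests, the 26 lists, the rule and all alternatives other than those said to be chosen later were fixed before the data were examined.

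Other alternatives were median-ratio size factors, upper-quartile normalisation, no expression filter, a minimum mean of 20 CPM, an adjusted p under 0.01, a replicate block, DESeq2 1.42.0, a model with the 2 genotypes compared alone, and leaving out each library in turn. The procedure was tested on simulated counts with the wild-type mean of each gene in every genotype, the real totals and 200 genes changed. The changes were put into a single knockout genotype per run. Apart from them and a shifted list, no gene differed between genotypes, a simpler setting than the real one. At a 1.5-fold change the procedure recovered 47% of the changed genes for DHX36 knockout against wild type (12195 genes in the run). It recovered 38% for FANCJ knockout (12210 genes) and 49% for the double knockout (12195 genes). For a 2-fold change these shares were 71%, 73% and 73%. Among unchanged genes 0.0584%, 0.0584% and 0.0751% were called, and of 25 unshifted lists camera called 0 in each of the 3 runs. The simulated genes varied independently of each other, so these runs do not show how often camera calls lists of correlated genes. Figures were drawn with matplotlib 3.10.9.

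Tags at the 3′ end report transcript levels and not the integrity of the coding region. Near-identical copies, such as the Usp17l and Zscan4 families, histone genes and ribosomal protein genes with many processed pseudogenes, can exchange reads, so single members of these families are uncertain. The same holds for overlapping transcripts of one locus, such as Meg3 and Mirg, or Airn and its antisense neighbour.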

Results

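Transcript levels were compared between wild-type mouse embryonic stem cells and cells lacking the G-quadruplex helicases DHX36, FANCJ or both, in 3 libraries per genotype. DHX36 unwinds G-quadruplexes, 4-stranded structures of guanine-rich sequence, in RNA and DNA. FANCJ, encoded by Brip1, is a DNA helicase that also acts in the Fanconi anaemia pathway of crosslink repair. The series concerns the control of G-quadruplex landscapes by RNA, and the expression data show how loss of each helicase, and of both together, altered transcript levels. Total counts ranged from 4284785 to 14721931 per library, and 15392 to 18441 genes had a count. Mitochondrial transcripts took 10.0% to 10.6% of counts in wild-type libraries, up to 12.3% in the DHX36 knockout, 11.2% to 11.5% in the FANCJ knockout and 11.9% to 13.2% in the double knockout. Ptma, the prothymosin alpha gene, took 7.06% to 8.56%. Libraries of one genotype differed by more than counting noise (chi-square per degree of freedom of 4.11 to 12.3), and each was counted as 1 replicate. Whether each knockout genotype was derived from 1 clone was not given in the sources used here, so an effect of a loss below is a difference between genotypes from which differences between clones are not separated. In a principal component analysis of the 500 most variable genes, the first component, with 51.1% of the variance, placed the 6 libraries without DHX36 on one side and the 6 with it on the other. The next component held 16.0%.

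The targeted transcripts were low in the genotypes named for them. Dhx36 (ENSMUSG00000027770, GRCm38 chromosome 3, 62468013 to 62507004, minus strand) had 247, 326 and 214 counts in wild type, 98, 56 and 126 in the DHX36 knockout, 444, 387 and 281 in the FANCJ knockout and 180, 189 and 163 in the double knockout. Its mean level was 54.1 ± 3.79 CPM (SD, n = 3) in wild type, 10.5 ± 1.45 in the DHX36 knockout, 55.6 ± 3.57 in the FANCJ knockout and 13.9 ± 1.54 in the double knockout. The log2 fold change against wild type was -2.35 (SE 0.13) in the DHX36 knockout and -1.97 (SE 0.12) in the double knockout. Brip1 (ENSMUSG00000034329, chromosome 11, 86058138 to 86201193, minus strand) had 31, 38 and 30 counts in wild type, 58, 47 and 75 in the DHX36 knockout, 1, 2 and 3 in the FANCJ knockout and 11, 4 and 2 in the double knockout. It fell by 4.45 (SE 0.45) on the log2 scale in the FANCJ knockout and by 3.93 (SE 0.36) in the double knockout. Each single knockout left the other gene within the spread between libraries (Dhx36 0.03, adjusted p = 0.935, and Brip1 0.01, adjusted p = 0.985). Which part of either gene was deleted was not given in the sources used here, so the residual 3′ tags do not show whether protein remained.

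**Figure D1:**
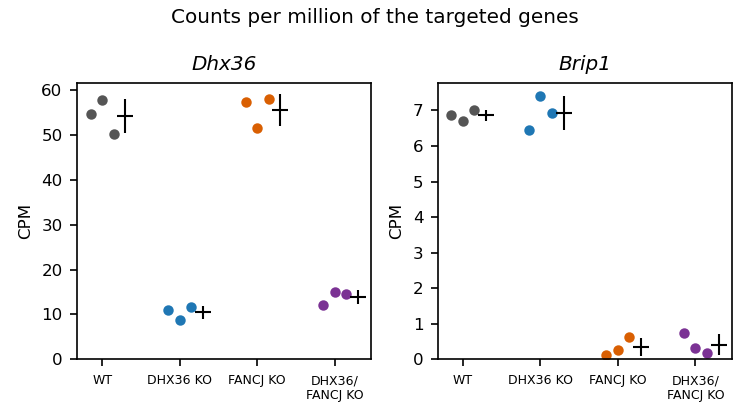
CPM of Dhx36 and Brip1 in each of the 12 libraries (points), with the mean and SD of the 3 libraries per genotype (bars); the vertical axes start at 0. Dhx36 was lower in the DHX36 and double knockouts, and Brip1 in the FANCJ and double knockouts.

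Loss of DHX36 alone raised formative and primed pluripotency genes and genes of the 2-cell-like state, and lowered the maternally expressed imprinted RNAs H19 and Meg3. Otx2, a transcription factor that drives the formative state, rose from 20.7 ± 6.82 to 97.1 ± 4.42 CPM (SD, n = 3), a log2 change of 2.23 (SE 0.15). The tetraspanin gene Cd37 (2.53, SE 0.17), the thyrotropin-releasing hormone gene Trh (2.41, SE 0.12) and Pfkp, which encodes the platelet isoform of the glycolytic enzyme phosphofructokinase (2.00, SE 0.11), rose beside it. Fam111a, a protease gene involved in replication, had the largest fall among the genes named (-2.79, SE 0.14, or 6.93-fold), from 58.8 ± 3.40 to 8.72 ± 2.43 CPM. H19 fell from 151 ± 5.71 to 35.7 ± 3.27 CPM (-2.08, SE 0.09), and Meg3 (-1.86, SE 0.11) and the simple-epithelial keratin Krt7 (-1.79, SE 0.14) fell as well.

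In all, 3113 of 12765 genes (24.4%) changed, 1628 up and 1485 down, of which 522 rose and 244 fell at least 2-fold (edgeR, adjusted p under 0.05), and 4591 passed an unadjusted p under 0.05. For 4805 genes (37.6%) the 3 knockout libraries lay all above or all below the 3 wild-type libraries, against 10% by chance. Further large rises were Psors1c2 (1.90), the Y-linked genes Ddx3y (1.81) and Eif2s3y (1.69), Dppa3 (1.68, SE 0.13), a naive pluripotency gene, Hebp1 (1.64), and Zscan4d (1.63), a marker of the 2-cell-like state. Large falls included the glutathione transferases Gstm2 (-1.76) and Gsto1 (-1.44), Cth (-1.67), which makes cysteine from cystathionine, Cited1 (-1.51) and Klhl13 (-1.47). The rule for naming passed over 17 predicted genes among the rises and 11 among the falls that ranked with these, 3 and 2 in the FANCJ knockout and 18 and 15 in the double knockout.

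Of the 26 gene lists, 9 differed from other genes in the DHX36 knockout, 3 up and 6 down, and 2 of them did so also with an estimated correlation between genes. Formative and primed pluripotency genes rose together, with 14 of 20 up and 1 down (15 and 1 adjusted over the list alone), a median of 0.63 and an adjusted p of 4.5e-07 (0.0444 with an estimated correlation). Besides Otx2 they included the de novo DNA methyltransferase Dnmt3a (1.51), the Wnt effector Lef1 (1.28) and the kinase Pim2 (1.16). The 2-cell-like genes rose, 8 of 14 up and 1 down (9 and 1 adjusted over the list alone), with a median of 1.12 and an adjusted p of 4.0e-05 (0.0287 with an estimated correlation), among them the deubiquitinase genes Usp17la (2.34) and Usp17lc (2.04). Fewer than 5 of them, the minimum for a list, reached 20 CPM, so the list was not tested among such genes. Its Usp17l and Zscan4 members can exchange reads.

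The remaining 7 lists passed with the preset correlation but not with an estimated one. Imprinted genes were lower, with 1 up and 12 down of 27 (1 and 12 adjusted over the list alone; adjusted p = 0.00745, and adjusted p = 0.0731 with an estimated correlation), led by H19, Meg3 and Mirg (-1.33). Among neuroectoderm markers 7 of 11 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.62 and Pax6 at -0.99 and Map2 at -0.99 (adjusted p = 0.00328, adjusted p = 0.111 with an estimated correlation, and 0.540 among genes of at least 20 CPM). Ribosomal protein genes were slightly lower (2 up and 16 down of 81, the same adjusted over the list alone, median -0.17, adjusted p = 7.6e-05, and adjusted p = 0.381 with an estimated correlation). Trophoblast markers had 2 up and 6 down of 16 (2 and 7 adjusted over the list alone) at an adjusted p of 0.0450, with Krt8 at -1.07 and Gata2 at 1.30. That adjusted p = 0.224 with an estimated correlation, 0.0644 at equal depth and 0.0565 with a replicate block. It was 0.0652, 0.0710 and 0.0646 without wild-type library 1, wild-type library 3 or knockout library 2. S-phase genes had 1 up and 4 down of 26 (1 and 4 adjusted over the list alone), with the polymerase subunit Pola1 at -0.71 and the helicase subunit Mcm2 at 0.59 (adjusted p = 0.0323). Their adjusted p = 0.406 with an estimated correlation, 0.107 among genes of at least 20 CPM, and 0.0790 and 0.109 without wild-type library 3 or knockout library 3. Cholesterol genes had 0 up and 4 down of 24 (0 and 2 adjusted over the list alone) at an adjusted p of 0.0450. For them adjusted p = 0.111 with an estimated correlation, and 0.0651, 0.0568, 0.0653 and 0.0559 without wild-type library 1 or 2 or knockout library 1 or 3. Glycolysis and hypoxia genes had 10 up and 1 down of 29 (11 and 1 adjusted over the list alone), with the hypoxia targets Pdk1 (1.00) and Bnip3 (0.98) beside Pfkp (adjusted p = 0.0451). Here adjusted p = 0.111 with an estimated correlation and 0.0518 with a replicate block. It was 0.115, 0.0790, 0.0715 and 0.0585 without wild-type library 2 or 3 or knockout library 1 or 3.

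The other 17 lists did not pass in the DHX36 knockout, although members of each changed. Naive pluripotency genes had 9 up and 3 down of 30 (10 and 3 adjusted over the list alone, adjusted p = 0.142), with Fbxo15 at 0.87, Tdgf1 at 0.73 and Nr0b1 at -0.71. ATF4 targets of the integrated stress response had 6 up and 2 down of 25 (7 and 2 adjusted over the list alone, adjusted p = 0.0920), with Ddit4 at 1.28 and Atf4 itself at 0.92. Primitive endoderm markers moved both ways, 4 up and 4 down of 17 (5 and 5 adjusted over the list alone, adjusted p = 0.932), with Sox17 at 2.10 and Gata6 at 1.12. Mesendoderm markers had 3 up and 0 down of 11 (3 and 0 adjusted over the list alone, adjusted p = 0.225), with Hand1 at 1.25, T at 1.06 and Eomes at 0.82. Among fibroblast markers 2 rose and 3 fell of 17 (2 and 3 adjusted over the list alone, adjusted p = 0.947), Thy1 rising by 1.91 and the contractile genes Tagln and Acta2 at -1.31 and -1.13. Restricted to genes of at least 20 CPM, the naive pluripotency and ATF4 lists reached an adjusted p of 0.0456 upward, the fibroblast list 0.0456 downward and the primitive endoderm list 0.0284 downward. Of the G-quadruplex helicases 4 rose and 2 fell of 21 (4 and 3 adjusted over the list alone, adjusted p = 0.947), the RNA helicase Dhx9 rising by 0.97. R-loop factors had 5 up and 3 down of 24 (5 and 4 adjusted over the list alone, adjusted p = 0.947), with the mRNA export helicase Ddx19b at 1.54. Fanconi and recombination genes had 3 up and 3 down of 28 (the same adjusted over the list alone, adjusted p = 0.902), with Fancd2 at 0.76 and Brca1 at -0.54. The p53 targets had 7 up and 6 down of 29 (the same adjusted over the list alone, adjusted p = 0.947).

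Immediate early genes had 1 up and 4 down of 19 (2 and 4 adjusted over the list alone, adjusted p = 0.890), with Spry4 at 1.24 and Dusp1 at -0.80. Wnt targets had 3 up and 0 down of 11 (3 and 0 adjusted over the list alone, adjusted p = 0.947), with Bmp4 at 1.24. Counts over all genes and adjusted over the list alone were 2 up with 3 down and 2 up with 4 down of 22 for germline genes (adjusted p = 0.204), and 3 up with 0 down and 2 up with 0 down of 15 for histones (0.353). They did not differ for G2 and mitosis genes (0 up and 2 down of 22, adjusted p = 0.638), interferon-stimulated genes (0 and 2 of 14, 0.947), endoplasmic reticulum chaperones (0 and 1 of 20, 0.947) and mitochondrial mRNAs (2 and 0 of 13, 0.204). In the DHX36 knockout the median was negative, the mean positive and the test downward for G-quadruplex helicases, p53 targets and primitive endoderm markers. For R-loop factors and Wnt targets only the median was negative. For fibroblast markers and chaperones the median and mean were positive and the test downward, and for interferon-stimulated and immediate early genes the median alone was positive.

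Genes with a G-quadruplex motif in the 3′ UTR, 1415 of 12239 searched, were slightly higher in the DHX36 knockout, with a median of 0.11 against -0.00 for other genes (adjusted p = 0.0351, and 0.00692 with an estimated correlation). The call ended after correction for UTR GC content (adjusted p = 0.109) or UTR length (0.0888), and without wild-type library 2 (0.0515) or knockout library 3 (0.0632). The difference of medians, 0.11 before, was then 0.09, 0.09, 0.11 and 0.09, so the call lay close to the threshold and the difference itself moved little. For the 1010 of 12059 genes with a motif in the 5′ UTR the adjusted p was 0.134, and 0.0179 with an estimated correlation.

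Loss of FANCJ alone changed far fewer genes, and raised primitive endoderm markers, 2-cell-like genes, p53 targets and, on balance, imprinted genes. H19, the maternally expressed RNA that fell without DHX36, rose here from 151 ± 5.71 to 639 ± 50.7 CPM (SD, n = 3), a log2 change of 2.08 (SE 0.09). The paternally expressed zinc finger gene Plagl1 rose from 18.1 ± 5.33 to 69.0 ± 7.35 CPM (1.96, SE 0.15), and Peg3 rose by 0.88 (SE 0.12). Dppa3, which protects maternal methylation marks in the early embryo, fell from 20.5 ± 3.18 to 7.18 ± 1.15 CPM (-1.53, SE 0.17), opposite to its rise in the DHX36 knockout. The mesoderm gene T fell by 2.28 (SE 0.25) and the endoderm genes Srgn and Sox17 rose by 3.41 (SE 0.25) and 2.42 (SE 0.35).

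In all, 264 genes (2.07%) changed, 185 up and 79 down, 52 and 13 of them at least 2-fold, while 1910 passed an unadjusted p under 0.05 (edgeR). For 2386 genes (18.7%) the groups did not overlap, against 10% by chance. Other rises were Ddx3y (1.39), Vgf (0.93), Zrsr1 (0.92), an imprinted splicing factor gene, Igfbp4 (0.91), Col4a1 (0.89) and the protease inhibitor Serpine2 (0.92). Falls included Mirg (-0.94) and Meg3 (-0.75) of one imprinted locus, the Nodal antagonist Lefty2 (-0.90), Fam98c (-0.81), Bcl3 (-0.72) and Sox15 (-0.72). Hmces (-0.78), Sh3bp1 (-0.77) and Sh3gl2 (-0.66) fell too, but their calls were lost without wild-type library 2 (adjusted p = 0.103, 0.176 and 0.175), knockout library 1 (0.0559, 0.119 and 0.0674) or knockout library 3 (0.0577, 0.0965 and 0.0714). That of Sh3gl2 was lost also without knockout library 2 (0.0823), and that of Sh3bp1 with the 2 genotypes fitted alone (0.0521). The count of changed genes was 130 and 131 without wild-type library 1 or 2, 110 and 143 without knockout library 1 or 3, 159 with the 2 genotypes fitted alone and 418 without an expression filter.

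Of the gene lists 11 differed from other genes in the FANCJ knockout, 6 up and 5 down, and 5 did so with either correlation. Markers of primitive endoderm, the lineage of the yolk sac, rose in 9 of 17 cases with 0 down (10 and 0 adjusted over the list alone), with a median of 0.83 (adjusted p = 5.5e-10, and 0.00822 with an estimated correlation). Gata6, a regulator of this lineage, was at 1.40, with a call lost without wild-type library 2 or 3 or knockout library 1 or 3 (adjusted p = 0.0634, 0.0685, 0.0638 and 0.0622). The p53 targets rose, 7 of 29 up and 0 down (11 and 0 adjusted over the list alone), among them the p53 antagonist Mdm2 (0.61, SE 0.08) and the translesion polymerase gene Polk (0.69, SE 0.12), with a median of 0.25 (adjusted p = 1.2e-09, and 0.00260 with an estimated correlation). For 2-cell-like genes the median was 0.74, with 3 up and 0 down of 14 (8 and 0 adjusted over the list alone, adjusted p = 5.5e-10, and 0.00260 with an estimated correlation). Again too few 2-cell-like genes reached 20 CPM for a test there. Their called members were Usp17lc (0.92) and Gm5662 (0.75), lost without wild-type library 1 (adjusted p = 0.0586 and 0.0531), and Zscan4d (0.64), lost without wild-type library 2 (0.140) or knockout library 1 or 2 (0.108 and 0.0855) and with the 2 genotypes fitted alone (0.0758). Imprinted genes rose on balance, 5 up and 2 down of 27 (10 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.00177, and 0.0216 with an estimated correlation). Naive pluripotency genes were lower, 0 up and 2 down of 30 (1 and 5 adjusted over the list alone, median -0.12, adjusted p = 0.00187, and 0.0216 with an estimated correlation), Dppa3 having the largest fall.

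For 6 lists the call was lost with an estimated correlation. Trophoblast markers had 1 up and 0 down of 16 (6 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.00342, and adjusted p = 0.0752 with an estimated correlation). Fibroblast markers had 3 up and 0 down of 17 (4 and 0 adjusted over the list alone, median 0.29, adjusted p = 0.00898, and adjusted p = 0.0530 with an estimated correlation), Acta2 rising by 0.53 (SE 0.09). ATF4 targets had 0 up and 2 down of 25 (2 and 8 adjusted over the list alone, median -0.13, adjusted p = 0.0129, and adjusted p = 0.0530 with an estimated correlation). S-phase genes had 0 up and 1 down of 26 (0 and 3 adjusted over the list alone, adjusted p = 0.0186). For these, adjusted p = 0.271 with an estimated correlation, and 0.133 and 0.149 without wild-type library 3 or knockout library 3. Fanconi and recombination genes had 0 up and 0 down of 28 (also adjusted over the list alone) with a median of -0.10 and an adjusted p of 0.0405 by camera. There, adjusted p = 0.0752 with an estimated correlation, and 0.0953, 0.0577 and 0.107 without wild-type library 1 or 2 or knockout library 2. Cholesterol genes had 0 up and 0 down of 24 (also adjusted over the list alone), a median of -0.11 and an adjusted p of 0.0498. That call was lost with an estimated correlation (adjusted p = 0.0877), size factors (0.0510), a minimum of 20 CPM (0.0762), and without wild-type library 1, 2 or 3 or knockout library 3 (0.116, 0.0793, 0.0501 and 0.149).

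The other 15 lists did not pass in the FANCJ knockout. Among mesendoderm markers 2 rose and T fell of 11 (2 and 1 adjusted over the list alone, adjusted p = 0.683, the mean negative with median and test positive). The Wnt target Sp5 fell by 1.13 (SE 0.21), with 0 up and 1 down of 11 in its list (1 and 1 adjusted over the list alone, adjusted p = 0.122, and 0.0356 without knockout library 1). The R-loop factor Thoc5, part of the mRNA export complex THO, fell by 0.64 (SE 0.11), the single call in a list of 24 (also adjusted over the list alone, adjusted p = 0.122). Lefty2 was the single call among 20 formative and primed genes (2 up and 3 down adjusted over the list alone, adjusted p = 0.153, and 0.0255 among genes of at least 20 CPM). Immediate early genes had 2 up and 1 down of 19 (5 and 2 adjusted over the list alone, adjusted p = 0.40), Egr1 falling by 0.85 (SE 0.14). Ribosomal protein genes had 1 up and 1 down of 81 (also adjusted over the list alone, adjusted p = 0.0825, and 0.00252 without wild-type library 3). Germline genes had 1 up and 0 down of 22 (2 and 0 adjusted over the list alone, adjusted p = 0.196). No member passed over all genes among neuroectoderm markers (1 up and 1 down of 11 adjusted over the list alone, adjusted p = 0.711) or histones (0 up and 1 down of 15 adjusted over the list alone, adjusted p = 0.122, and 0.0453 and 0.0350 without wild-type library 3 or knockout library 3). None passed either way among G-quadruplex helicases (21 tested, adjusted p = 0.196), G2 and mitosis genes (22, 0.130), interferon-stimulated genes (14, 0.579), chaperones (20, 0.113, and 0.0108 among genes of at least 20 CPM), glycolysis and hypoxia genes (29, 0.253) and mitochondrial mRNAs (13, 0.130). Neither motif set passed the test (adjusted p = 0.882 for both), with median differences of 0.02 for the 5′ UTR and 0.01 for the 3′ UTR.

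Loss of both helicases lowered fibroblast and neuroectoderm markers and raised naive pluripotency genes. Acta2, the smooth muscle actin gene, fell from 363 ± 41.9 to 45.8 ± 4.79 CPM (SD, n = 3), a log2 change of -2.98 (SE 0.10). The collagen gene Col1a1 (-2.59, SE 0.11) and the actin-binding genes Tagln (-2.32, SE 0.10) and Cnn1 (-1.99, SE 0.18) fell with it, as did Wls, needed for Wnt secretion (-2.12, SE 0.12). Cd37 (3.11, SE 0.17), Otx2 (2.61, SE 0.15) and Pfkp (2.09, SE 0.11) rose as in the DHX36 knockout, and H19 (1.98, SE 0.09) as in the FANCJ knockout. Ak4 (2.25, SE 0.10), a mitochondrial adenylate kinase gene induced by hypoxia, and Acaa2 (2.15, SE 0.17), of fatty acid oxidation, rose too.

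In all, 4331 genes (33.9%) changed, 2119 up and 2212 down, 704 and 620 of them at least 2-fold, and 5535 passed an unadjusted p under 0.05 (edgeR). For 5773 genes (45.2%) the groups did not overlap, against 10% by chance. Further named rises were Ddx3y (2.07), the ephrin receptor Epha4 (1.96), Aard (1.88, SE 0.24) and the sodium pump subunit Atp1b2 (1.83). Further falls were Fam111a (-2.24), Acta1 (-2.05), the imprinted gene Nnat (-2.01) and Cited1 (-1.97).

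**Figure D2:**
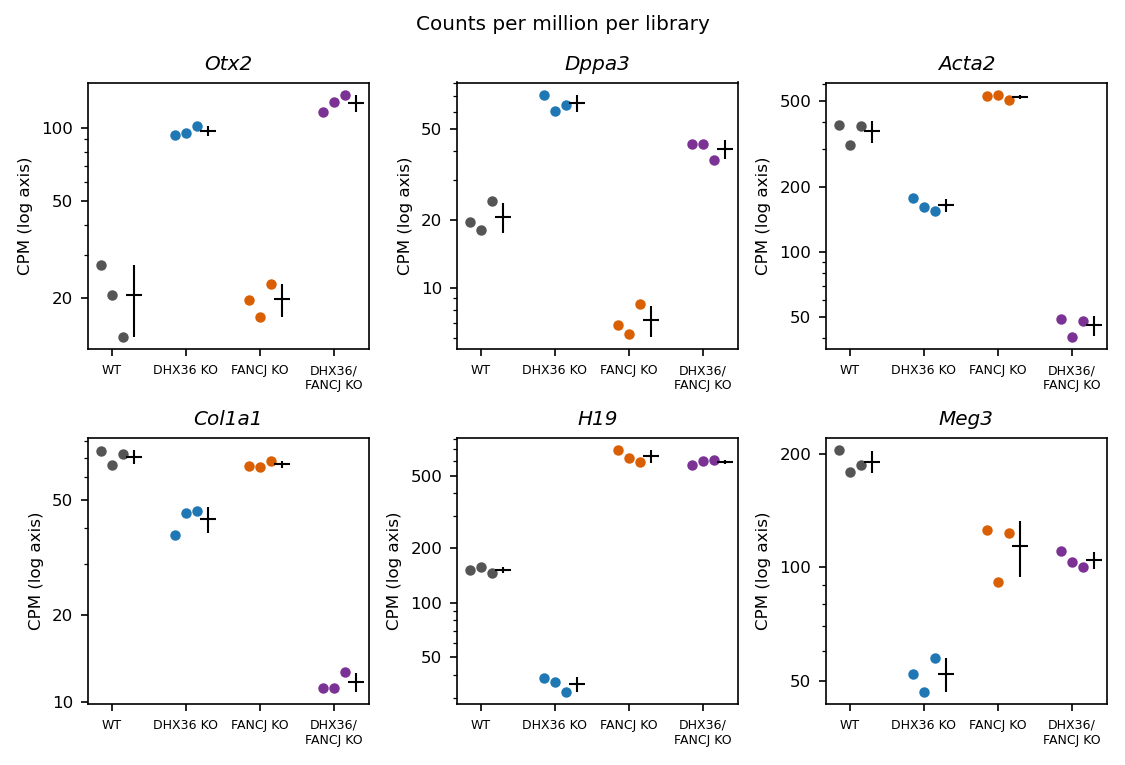
CPM of Otx2, Dppa3, Acta2, Col1a1, H19 and Meg3 in each library (points) with the mean and SD of the 3 libraries per genotype (bars), on log axes. Otx2 was high in both genotypes without DHX36, H19 was low in the DHX36 knockout and high in both genotypes without FANCJ, and Acta2 and Col1a1 were lowest in the double knockout.

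In the double knockout 8 gene lists differed from other genes, 3 up and 5 down, and 3 held with either correlation. Naive pluripotency genes rose, 18 of 30 up and 3 down (19 and 3 adjusted over the list alone), with a median of 0.31 (adjusted p = 1.3e-04, and 0.0279 with an estimated correlation). They included Fbxo15 (1.40), Tbx3 (1.31) and Dppa3 (1.01), while Tdh, threonine dehydrogenase, fell by 1.15. Neuroectoderm markers fell, 0 up and 9 down of 11 (the same adjusted over the list alone), with a median of -0.92 and the neuronal genes Nefl (-1.61) and Gap43 (-1.28) among them (adjusted p = 9.5e-06, and 0.0304 with an estimated correlation). Fibroblast markers fell, 1 up and 10 down of 17 (the same adjusted over the list alone, median -0.77, adjusted p = 1.3e-04, and 0.0279 with an estimated correlation), led by Acta2, Col1a1, Tagln and Timp3 (-1.85).

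The other 5 calls were lost with an estimated correlation. Formative and primed genes had 11 up and 1 down of 20 (the same adjusted over the list alone, median 0.49, adjusted p = 0.00150, and adjusted p = 0.164 with an estimated correlation), with Zic2 at 1.48, Dnmt3a at 1.47 and Cldn6 at -1.45. Immediate early genes had 2 up and 11 down of 19 (2 and 12 adjusted over the list alone, median -0.43, adjusted p = 7.9e-04, and adjusted p = 0.0554 with an estimated correlation), with Ier3 at -1.58, Junb at -0.99 and Dusp1 at -0.90. Ribosomal protein genes had 2 up and 27 down of 81 (the same adjusted over the list alone, median -0.18, adjusted p = 7.9e-04, and adjusted p = 0.417 with an estimated correlation). Wnt targets had 2 up and 7 down of 11 (the same adjusted over the list alone, median -0.59), with Sp5 at -2.84, Nkd1 at -1.44 and Ccnd1 at -1.09 (adjusted p = 0.0288). Their adjusted p = 0.190 with an estimated correlation and 0.0581 without wild-type library 3. Mitochondrial mRNAs had 4 up and 0 down of 13 (the same adjusted over the list alone, median 0.26), with mt-Nd2 at 0.67 (adjusted p = 0.0389), in libraries where mitochondrial transcripts took 11.9% to 13.2% of counts against 10.0% to 10.6% in wild type. For these, adjusted p = 0.257 with an estimated correlation, and 0.102, 0.0775, 0.0793 and 0.0559 without wild-type library 1 or 3 or knockout library 1 or 2.

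The other 18 lists did not pass in the double knockout, although some held large changes in both directions. Imprinted genes had 5 up and 11 down of 27 (6 and 13 adjusted over the list alone, adjusted p = 0.101), with H19 up and Nnat and Peg10 (-1.32) down. Primitive endoderm markers had 6 up and 3 down of 17 (7 and 3 adjusted over the list alone, adjusted p = 0.512), with Srgn at 3.06 and Sox17 at 1.96. Mesendoderm markers had 3 up and 2 down of 11 (the same adjusted over the list alone, adjusted p = 0.953), with Wnt3 at -2.31, T at -1.25 and Meis2 at 1.39. Trophoblast markers had 6 up and 6 down of 16 (7 and 6 adjusted over the list alone, adjusted p = 0.953), the keratins Krt8 (-1.90), Krt7 (-1.79) and Krt18 (-1.77) and the transcription factor Cdx2 (-2.24) being the largest. Interferon-stimulated genes had 4 up and 4 down of 14 (the same adjusted over the list alone, adjusted p = 0.953), with Cxcl10 at -2.49 and Bst2 at -2.02. The p53 targets had 8 up and 6 down of 29 (8 and 7 adjusted over the list alone, adjusted p = 0.694), with Sesn1 at 1.41 and Sesn2 at 0.98. ATF4 targets had 8 up and 3 down of 25 (the same adjusted over the list alone, adjusted p = 0.327), with Ddit4 at 1.24 and Phgdh, of serine synthesis, at -1.24. Glycolysis and hypoxia genes had 6 up and 5 down of 29 (7 and 5 adjusted over the list alone, adjusted p = 0.757), with Ndrg1 at 1.37. Germline genes had 5 up and 2 down of 22 (the same adjusted over the list alone, adjusted p = 0.0796), with Taf7l at 2.65 and Stra8 at 1.51. The 2-cell-like genes had 4 up and 0 down of 14 (the same adjusted over the list alone, adjusted p = 0.127), with Usp17la at 1.41 and Zscan4d at 1.03.

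G-quadruplex helicases had 2 up and 3 down of 21 in the double knockout (1 and 3 adjusted over the list alone, adjusted p = 0.924), with Dhx9 at 1.02. R-loop factors had 3 up and 2 down of 24 (the same adjusted over the list alone, adjusted p = 0.953), with Ddx19b at 1.36. Fanconi and recombination genes had 3 up and 3 down of 28 (2 and 2 adjusted over the list alone, adjusted p = 0.953), with Rbbp8 at 0.86. S-phase genes had 0 up and 5 down of 26 (the same adjusted over the list alone, adjusted p = 0.0649, and 0.0442 without wild-type library 1), with Slbp at -0.49. G2 and mitosis genes had 5 up and 1 down of 22 (4 and 1 adjusted over the list alone, adjusted p = 0.512). Histones had 4 up and 0 down of 15 (the same adjusted over the list alone, adjusted p = 0.0642, and 0.0403 without knockout library 1), with Hist1h2bc at 1.52. Cholesterol genes had 0 up and 5 down of 24 (the same adjusted over the list alone, adjusted p = 0.0832). Chaperones had 4 up and 2 down of 20 (the same adjusted over the list alone, adjusted p = 0.953), with Hspa5 at 0.41. In this comparison the median was negative with mean and test positive for R-loop factors, p53 targets and glycolysis and hypoxia genes. Both median and mean were negative with the test upward for interferon-stimulated genes. The mean alone was negative for mesendoderm markers, the median alone positive for trophoblast markers, and the mean alone positive for chaperones. Neither motif set passed the test here (adjusted p = 0.450 for both, median differences of 0.04 for the 5′ UTR and 0.05 for the 3′ UTR). By camera 0 of the sets passed in the double or FANCJ knockout with either correlation, the smallest unadjusted p with the preset correlation being 0.351 and 0.538.

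**Figure D3:**
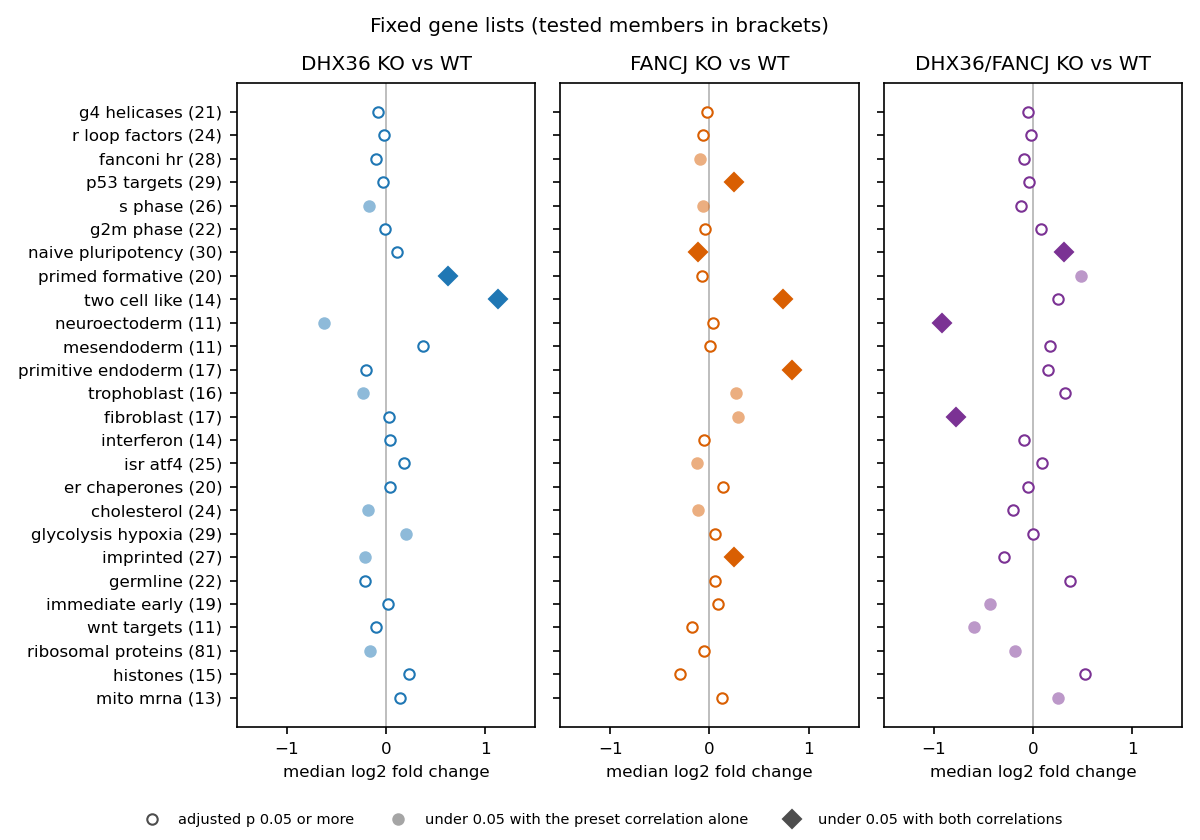
Median log2 fold change against wild type of the tested members of each of the 26 gene lists (number tested in brackets) in the 3 knockout genotypes. Open circles had an adjusted p of 0.05 or more, filled circles were under 0.05 with the preset correlation alone and diamonds with both correlations; primitive endoderm markers in the FANCJ knockout (0.83) and neuroectoderm markers in the double knockout (-0.92) lie far from 0.

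The double knockout was compared with the DHX36 knockout to see the effect of FANCJ loss without DHX36, which raised H19 and lowered Col1a1 and Acta2 further. H19 rose by 4.06 (SE 0.10), from 35.7 ± 3.27 CPM in the DHX36 knockout to 594 ± 17.9 in the double knockout (SD, n = 3). Aass, of lysine breakdown (2.41, SE 0.17), the X-linked homeobox gene Rhox5 (2.01, SE 0.11), Arl14epl (1.82) and the secreted phosphoprotein Spp1 (1.81) rose with it. Col1a1 (-1.87, SE 0.11), Acta2 (-1.85, SE 0.10), the neuronal growth gene Dpysl2 (-1.70), the insulin receptor substrate Irs1 (-1.69) and the metalloproteinase inhibitor Timp3 (-1.57) fell. In this comparison 2512 genes (19.7%) changed, 1057 up and 1455 down, 224 and 319 at least 2-fold, and 4706 (36.9%) did not overlap, against 10% by chance. Dhx36 itself was at 0.39 (adjusted p = 0.0456), a call lost in 9 alternatives, with adjusted p of 0.0832, 0.175, 0.161 and 0.103 without DHX36 knockout library 1 or 2 or double knockout library 2 or 3, and 0.0544 to 0.0755 in the others.

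Removing DHX36 from cells that lacked FANCJ gave the largest count. Here 4697 genes (36.8%) changed, 2332 up and 2365 down, 662 and 736 at least 2-fold, and 6219 (48.7%) did not overlap, against 10% by chance. Acta2 fell by 3.52 (SE 0.10), from 524 ± 13.5 to 45.8 ± 4.79 CPM (SD, n = 3), and Tagln (-2.70), Col1a1 (-2.50) and Wls (-2.49) fell with it. Cd37 (3.13), Otx2 (2.69), Dppa3 (2.54), Pfkp (2.21) and Aass (2.15) rose.

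The interaction asked for which genes the effect of FANCJ loss depended on DHX36. It was past the threshold for 1122 genes (8.79%), 348 positive and 774 negative. For 899 of them FANCJ loss had estimates of opposite sign with and without DHX36, but both estimates were called for only 56. Choosing genes because these effects differ by itself favours opposite signs, so the 899 do not show how many effects were reversed. Acta2 rose by 0.53 on FANCJ loss with DHX36 present and fell by 1.85 without it, an interaction of -2.38 (SE 0.14). Pmp22, a peripheral myelin gene (-2.25, SE 0.13), and Igfbp4 (-1.86, SE 0.23), which binds insulin-like growth factors, followed the same course. Meg3 (1.75, SE 0.15) and Mirg (1.86, SE 0.21) fell on FANCJ loss with DHX36 present and rose without it, and H19 rose in both settings, by 2.08 and 4.06 (interaction 1.98, SE 0.12). For Aass (2.89, SE 0.25), Rhox5 (1.93, SE 0.17), Irs1 (-2.12, SE 0.24) and Timp3 (-1.83, SE 0.19), FANCJ loss passed the threshold only without DHX36, and here the interaction itself tested the difference.

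Across the 12765 genes, which are not independent replicates, the effects of DHX36 loss with and without FANCJ had a Pearson r of 0.584 (Spearman's rho 0.556), against -0.004 in 20 simulations without effects; these fold changes share no library. Of the calls, 956 were up in both settings against 297 for independent lists, and 935 down against 275. The effects of FANCJ loss with and without DHX36 had an r of 0.150 and a rho of 0.0749 (simulated r -0.002). FANCJ loss with DHX36 present changed 264 genes, against 3113 for DHX36 loss with FANCJ present. Noise lowers r more where effects are few, so the lower r does not by itself show weaker agreement of the effects. Here 48 genes were up in both settings against 15.3 for independent lists and 24 down against 9.0. By contrast, 52 of the 185 genes that rose with DHX36 present fell without it, against 21.1 for independent lists, and 4 of the 79 that fell rose, against 6.54. The DHX36 and FANCJ knockouts compared with the same wild-type libraries had an r of 0.301 (rho 0.179), where simulated unchanged groups gave 0.569 (0.555 to 0.584) from the shared controls alone. Their covariance was 0.0760 against a simulated 0.0357, a difference of 0.0403. That r was 0.456 and 0.454 without wild-type library 1 or 2, and 0.0682 among genes of at least 20 CPM. Calls up in both knockouts numbered 51 against 23.6 for independent lists, and those down 32 against 9.19. The simulations gave 0.05 and 0, but without effects hardly any gene is called, so these values are no measure for shared calls. In opposite directions, 52 rose in the FANCJ knockout and fell in the DHX36 knockout, against 21.5 for independent lists, and 13 fell in the former and rose in the latter, against 10.1. The 3 wild-type libraries were not split, since 1 part would hold a single library, and part of the shared calls may come from them.

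**Figure D4:**
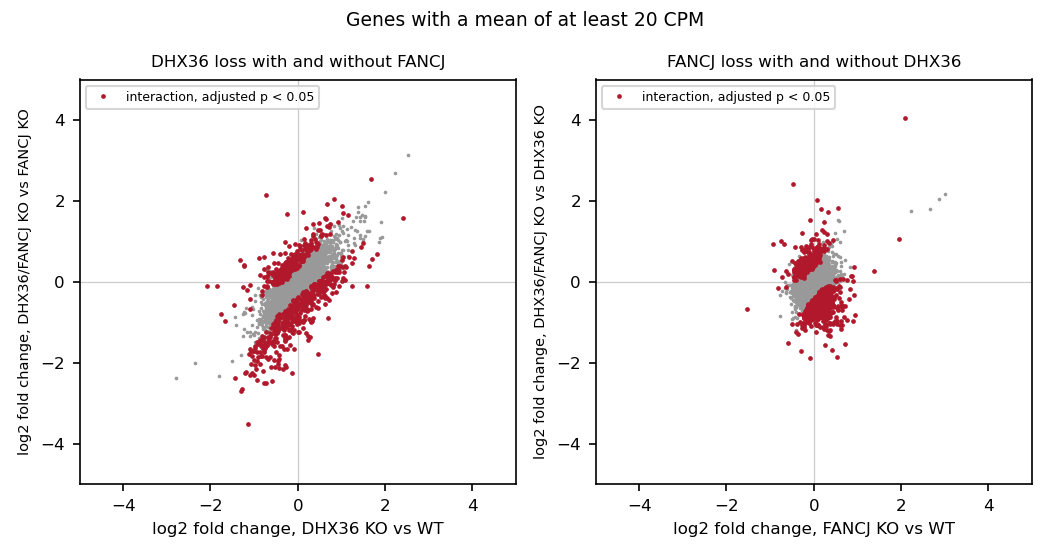
Log2 fold changes of the 5701 genes with a mean of at least 20 CPM for loss of DHX36 with FANCJ present (horizontal) and absent (vertical), left, and for loss of FANCJ with DHX36 present and absent, right. Each point is a gene, and the 690 with an adjusted p under 0.05 for the interaction are red. The effects of DHX36 loss lie along the diagonal more than those of FANCJ loss (r of 0.584 and 0.150 over all tested genes). Fewer genes changed on FANCJ loss with DHX36 present, and noise lowers r more there.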

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

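The counts over other splits of the libraries were planned, and the genes below were taken by the rule for named genes, while the comparison of the spread between splits was chosen only after the result was seen. The effect of FANCJ loss differed with the presence of DHX36, by the test of the interaction itself, for 10 named genes, the 5 largest differences in each direction. On the log2 scale, the effect without DHX36 minus that with it was 2.89 for Aass (-0.48 with DHX36, adjusted p = 0.231, and 2.41 without), 1.98 for H19 (2.08 and 4.06), 1.93 for Rhox5 (0.08, adjusted p = 0.825, and 2.01), 1.86 for Mirg (-0.94 and 0.92) and 1.75 for Meg3 (-0.75 and 1.00). Meg3 and Mirg are imprinted RNAs of one locus and H19 belongs to another. In the other direction the difference was -2.38 for Acta2 (0.53 and -1.85), -2.25 for Pmp22 (0.72 and -1.53), -2.12 for Irs1 (0.43, adjusted p = 0.210, and -1.69), -1.86 for Igfbp4 (0.91 and -0.96) and -1.83 for Timp3 (0.26, adjusted p = 0.354, and -1.57). All 10 kept their call in every alternative run. Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many interaction genes as the real 1122. The highest of the others gave 27. Those splits mixed genotypes, which put the genotype effects into the spread: the common dispersion was 0.00922 in the real split and 0.0235 to 0.0588 in the others. Their counts therefore bear on whether the genotypes differed at all, and chance is neither excluded nor shown for the interaction by them.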

How the results depend on the processing

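Thinning to equal depth and the correction for UTR length were chosen only after the data were seen, and all other alternatives were planned. Of 301 calls of named genes, 0 changed direction in any alternative that tested the gene, 235 held in every such alternative and 66 were lost at least once. A gene absent from a fit was passed over and not counted as lost. With the minimum of 20 CPM, 222 of 316 named entries, called or not, were unchanged and 2 were lost. The rest were not tested there. Losses, counted once per gene and fit, numbered 211 when 1 library was left out, 19 at equal depth, 15 with the 2 genotypes alone, 14 with DESeq2, 8 with a replicate block, 7 without a filter, 2 among genes of at least 20 CPM and 1 with upper-quartile scaling. The 19 calls lost at equal depth missed the threshold in a random thinning to the total of the shallowest library. Some missed it narrowly, such as Cdt1 in the FANCJ knockout (adjusted p = 0.0536, edgeR), and others widely, such as Rec8 in the DHX36 knockout (0.409). A call lost in this way does not show that the difference was absent.

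Counts of changed genes were 1839 (DHX36 knockout), 77 (FANCJ knockout), 2804 (double knockout), 1409 (double against DHX36 knockout) and 566 (interaction) at an adjusted p under 0.01. Among genes of at least 20 CPM, where fewer genes were tested, they were 1764 (DHX36 knockout), 2292 (double knockout), 1378 and 2435 (double against DHX36 and FANCJ knockout) and 741 (interaction). The FANCJ knockout count was 418 without a filter, where more genes were tested, and 159 with 2 genotypes alone, where fewer libraries estimated the spread. Leaving out 1 library gave 2503 to 2700, 110 to 198 and 3498 to 3940 genes for the 3 comparisons with wild type, 1789 to 2115 and 3869 to 4206 for the double against the DHX36 and FANCJ knockouts, and 880 to 1071 for the interaction. At equal depth the counts were 2671, 212 and 3572 against wild type, 1744 and 3671 for the double against the DHX36 and FANCJ knockouts, and 826 for the interaction, each lower than at full depth.

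With an estimated correlation 2, 5 and 3 lists passed in the DHX36, FANCJ and double knockouts, and 6 to 8, 9 to 12 and 6 to 8 when 1 library was left out. For G-quadruplex motifs in the DHX36 knockout, 2 sets passed with an estimated correlation, 0 with the GC or the length correction, and 0 to 1 without 1 library. For FANCJ loss with and without DHX36 the correlation of fold changes was 0.0749 as Spearman's rho, 0.133 as Pearson's r among genes of at least 20 CPM and 0.106 to 0.152 without 1 library. For DHX36 loss these values were 0.556, 0.669 and 0.524 to 0.570. For both knockouts against the same wild type they were 0.179, 0.0682 and 0.282 to 0.456, and 0.204 at equal depth. The cause was not tested for these moves.

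Replicate numbers did not pair the libraries: deviations of the 18 same-numbered pairs correlated at -0.120 to 0.120, 3 of them over 0.1, and 4 of 12 libraries correlated best with their own number. A replicate block gave 3004, 233 and 4264 changed genes against wild type, ended the glycolysis (adjusted p = 0.0518) and trophoblast (0.0565) calls in the DHX36 knockout, and with the GC correction left 0 motif sets.

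The 10 splits of 2 groups of 3 are too few for a share under 0.05. All but the real one mixed genotypes, which puts the genotype effects into the spread and lowers the counts of changed genes. The contrast of these counts is therefore no measure of chance. The real split, 1 of 10, gave 3113, 264, 4331, 2512 and 4697 changed genes, and the highest of the others 1, 2, 0, 0 and 0. For lists it gave 9, 11 and 8, and the highest of the others 3, 4 and 3. For motif sets it gave 1, 0 and 0 against 0 for the others, so that in the FANCJ and double knockouts all 10 splits gave as many.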

Other observations

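The 4 gene lists, the family of predicted genes with its limit on shared sequence, and the tests of explanations in this part were chosen only after the results were seen, except for the test with receptor genes. Members of the actin and keratin lists include genes already seen to fall, such as Acta2, Tagln and Krt8. The p-values of those lists are lowered by that choice and only describe the data. Genes of the actin cytoskeleton and targets of its transcription factor SRF were lower in both genotypes without DHX36. Of 37 tested, 1 rose and 28 fell in the DHX36 knockout (median -0.70, adjusted p = 1.9e-15 by camera, and 9.1e-05 with an estimated correlation). In the double knockout 0 rose and 31 fell (median -1.16, 4.9e-23, and 1.9e-05 with an estimated correlation). The regulatory myosin light chain Myl9 was at -2.44 and -3.21, tropomyosin Tpm1 at -0.84 and -1.57, and filamin Flna at -0.82 and -1.39. In the FANCJ knockout 3 rose and 0 fell (median 0.04, adjusted p = 0.164), whereas between the double and the DHX36 knockout 27 fell (median -0.46, 1.6e-14), and between the double and the FANCJ knockout 32 fell (median -1.34, 1.4e-22). Simple epithelial keratin and junction genes took a similar course, with 0 up and 12 down of 16 in the DHX36 knockout (median -0.78, adjusted p = 4.3e-08, and 0.0130 with an estimated correlation). They had 1 up and 0 down in the FANCJ knockout (median 0.17, adjusted p = 0.0518) and 0 up and 14 down in the double knockout (median -1.37, 1.0e-12, and 0.00304 with an estimated correlation). Krt18 (-0.96 and -1.77 in the DHX36 and double knockouts), the desmosome gene Dsp (-0.78 and -1.40) and the tight junction gene Ocln (-0.85 and -1.67) were among them.

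Fatty acid oxidation genes had 6 up and 1 down of 19 in the DHX36 knockout (adjusted p = 0.301), 0 up and 0 down in the FANCJ knockout (0.317 by camera) and 6 up and 2 down in the double knockout (0.0593). Between the double and FANCJ knockouts 7 rose and 0 fell (0.00999, and 0.0263 with an estimated correlation). The mitochondrial carnitine palmitoyltransferase Cpt1a was at 1.53 and 1.74 in the DHX36 and double knockouts, and the carnitine carrier Slc25a20 at 0.64 and 1.68. Nuclear RNAs had 0 up and 3 down of 10 in the DHX36 knockout (adjusted p = 0.301), 1 up and 1 down in the FANCJ knockout (0.40) and 6 up and 2 down in the double knockout (0.131). Their median was 0.48 between the double and the DHX36 knockout (adjusted p = 9.8e-04, but adjusted p = 0.0858 with an estimated correlation). Xist was at 1.40 and Neat1 at 0.59 in the double knockout.

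As an explanation for the lower actin and SRF target genes, fewer fibroblast-like cells stay open in both genotypes. In the DHX36 knockout the 15 fibroblast markers outside the actin list had a median of 0.12 (SE 0.25). In the double knockout it was -0.57 (SE 0.35). Among genes of at least 20 CPM the whole fibroblast list was lower in the DHX36 knockout (adjusted p = 0.0456 by camera). Its 5 members outside the actin list had a median of 0.03 (SE 0.21), so they did not fall together. But Col1a1, the lowest at -0.72, fell about as far as the actin median of -0.70. These SEs were taken over genes, and the markers under 20 CPM can report little loss. Fewer differentiated cells of every kind would lower the markers of each lineage. In the double knockout 9 called primitive endoderm and mesendoderm markers rose and 5 fell. Of the called neuroectoderm markers 0 rose and 9 fell (Fisher's exact p = 0.00261). In the DHX36 knockout the counts were 7 up and 4 down against 1 up and 7 down (Fisher's exact p = 0.0587). Fisher's test counts markers as independent, but those of one lineage may vary together, so its p-values do not measure the spread between libraries. The called rises argue against a fall of every lineage in the double knockout, while a fall of some stays open. The explanation stays open in the DHX36 knockout. Lower SRF activity reaching immediate early genes stays open in both. By camera with an estimated correlation that list had an adjusted p of 0.911 in the DHX36 knockout and 0.0554 in the double knockout. Only a rise of the list was set to count against the explanation, so the test could hardly do so. The list's median was 0.02 in the DHX36 knockout, against -0.70 for the actin genes. In the double knockout it was -0.43 against -1.16. An effect of DHX36 loss on actin gene expression may remain among the open explanations, and was not tested apart from the genotype itself or from differences between clones.

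Predicted genes that share sequence with Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301), defined by at least 10% of their 25-base words, were higher in the double knockout than in wild type, with 10 of 10 tested called up, a median of 3.80 and the lowest at 2.80. Their summed level was 78.0, 31.4 and 124 CPM in wild type, 491, 183 and 177 in the DHX36 knockout, 1168, 140 and 324 in the FANCJ knockout and 1554, 1021 and 1017 in the double knockout. Median changes were 1.91 (4 called) and 2.93 (6 called) in the DHX36 and FANCJ knockouts. The FANCJ knockout change leaned on library 1, at 1168 CPM. Since these genes share sequence, they can exchange reads, and their calls are not independent of each other. A larger share of nuclear RNA as the whole cause is argued against by a median of 0.47 (SD 0.71) for nuclear RNAs. Of these 10, 6 were called up and 2 down, so such a share as part of the cause stays open. Some, such as Meg3, may respond to the genotypes themselves, so their median is a rough gauge. Genomic DNA in the libraries stays open. The summed CPM of 1466 olfactory and vomeronasal receptor genes changed by 0.72 (SE 0.15), a rise that DNA would also give. They already had 45.5 to 64.4 CPM in wild type, which can lower that ratio. How often the family's sequence occurs in the genome was not counted, so the test could not count against DNA. Depth is argued against by a median of 3.79 at equal depth, where 9 of 9 tested stayed called. The median of the nuclear RNAs lay far below the family's change, while the handling of reads with several alignments is not known. Loss of the helicases may raise transcripts of these sequences, a hypothesis found and tested on the same data. Genomic DNA and differences between clones stay open beside it.

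The Y-linked genes Ddx3y and Eif2s3y were higher in each knockout genotype than in wild type, by 1.81 and 1.69, 1.39 and 0.62, and 2.07 and 1.19 in the DHX36, FANCJ and double knockouts. Fewer wild-type cells with a Y chromosome would raise both alike, which is in line with the DHX36 knockout, where they differed by 0.12 (SE 0.21). In the FANCJ and double knockouts they differed by 0.76 (SE 0.22) and 0.89 (SE 0.20). This goes against fewer such cells as the whole cause there, provided neither gene shares reads with its X-linked copy. For Ddx3y such reads are argued against by its ratio to Ddx3x, whose smallest change over the 3 comparisons was 1.39 (SE 0.18). For Eif2s3y this was not tested, so the difference between the genes does not settle the matter. Y loss in the wild-type culture may remain as a part or the whole of the cause. So may an effect of the genotypes or of the cells from which they were derived, which these libraries cannot separate.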
